A study of Mus musculus with 2 samples.

How the data were processed

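Tumours of mice bearing the mesothelioma line AB1-HA were dissociated with collagenase and DNase, dead cells were excluded with propidium iodide, and CD45-positive cells were sorted, per the labels' protocols. One library came from mice given a control antibody and 1 from mice given an anti-VEGF antibody, both with the 10x Genomics single cell 3-prime chemistry. The number of mice behind each library is not given in the sources used here. The deposited values are raw UMI counts per gene and cell barcode, not normalised. They were made with Cell Ranger 3.0.2 and genome build mm10 per the submitters' processing notes, while the software version per the file headers is 3.1.0. Barcodes had been called as cells before deposit, with at least 500 UMIs each. The matrices have 31053 features, of which 71 share a symbol, and 35 barcode sequences occurred in both libraries and were kept apart by library.

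The design, the filters, the gene lists, the marker lists, the rule for named genes and most alternative settings were fixed before the data were examined. Cells were kept with at least 300 detected genes, at least 500 UMIs and at most 10% mitochondrial UMIs, which left 10805 control and 8159 anti-VEGF cells (92.5% of barcodes in each). Scrublet, run within each library through scanpy 1.11.5, set thresholds of 0.55 and 0.623 and called 1 and 0 doublets. It therefore removed almost nothing, and any doublets among the deposited barcodes that passed the filter remain among the 18963 cells analysed. There were 2 other treatments: removal of 453 cells with markers of T cells and of another lineage, fixed beforehand, and removal of the top Scrublet scores of each library at 0.8% per 1000 barcodes, 934 and 533 cells (8.64% and 6.53%), which was added after the data were seen.

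Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes (without ribosomal, mitochondrial, immunoglobulin, T-cell receptor, Xist and Y-linked genes) gave 30 principal components, and a graph of 15 neighbours was clustered by Leiden at resolution 1.0 without batch integration. The 23 clusters were scored on 23 fixed marker classes. A cluster took a class name when at least 3 markers were each detected in 25% of its cells, their mean log2 fold over the other cells reached 1.5 and no other class had more markers among the 10 leading genes. For macrophages, at least 5 of 9 markers had to be detected in 50% of cells, with the same condition on leading genes. Other clusters with a median UMI count below the library median divided by 3, in both libraries, stayed unnamed as low-UMI clusters. Clusters 11 and 13 were called Acp5-high after their leading genes, and cluster 0 met no rule and stayed unnamed. These thresholds and the Acp5-high name were set after the data were seen. T and NK cells were clustered again by the same steps, and sub-clusters with at least 5 of the 9 macrophage markers in 50% of cells were kept apart as mixed, including 1 led by Foxp3 (23 and 13 cells). By these rules no regulatory T cell, B cell, plasma cell, eosinophil, endothelial or mural class was formed.

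UMIs were summed per class and library and divided by the total of the class to give CPM (counts scaled to a common total), with exact Poisson intervals for levels, exact conditional binomial intervals for ratios and exact (Clopper-Pearson) binomial intervals for shares, all at 95%. The log2 ratio used a pseudocount of 1 CPM. Expression was compared in 5 groups, the named classes and cluster 0 where each library had at least 100 cells. The low-UMI clusters, which had no class, and the mixed cells were left out of it. For each of 27 gene lists, the median log2 ratio over members with at least 30 UMIs was placed among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these libraries and is not a test. Symbols of 8 list members were not found among the features. Named genes are members of the fixed lists or markers, or the 6 highest and 6 lowest log2 ratios of a class among genes with at least 50 CPM in 1 library and detected in 10% of its cells, leaving out predicted, mitochondrial, ribosomal, haemoglobin, immunoglobulin, T-cell receptor, Xist and Y-linked genes. Leading genes of clusters are given to identify them and not as results. Shares of cells with a UMI were compared after thinning each cell to 5000 UMIs.

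The ratio and list steps were tested on simulated counts for the macrophage-like class over 13343 genes. The interval lay on the right side of 1 for 100% of 25 genes simulated at 2-fold, 88.0% at 1.5-fold and 76.0% at 1.25-fold, with median estimates of 1.98, 1.50 and 1.24. For unchanged genes, 95.0% of intervals held 1. A list of 20 genes simulated at 1.5-fold had a median ratio of 1.45, and 4.5% of unchanged lists fell outside the central 95%. Counts were drawn independently for each gene from a profile pooled over both libraries. Genes that vary together and variation between cells were therefore not simulated, and these rates do not carry over to the real lists.

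The totals of 233687412 and 213948867 UMIs make counting intervals narrow for abundant genes, and these intervals hold nothing of the variation between mice. The median of all genes lay below 0 in each class (log2 ratio -0.088 in macrophage-like and -0.12 in collagen-expressing cells). TMM factors (edgeR 4.0.16 in R 4.3.3) moved log2 ratios, before the pseudocount, by 0.11 in macrophage-like and 0.14 in collagen-expressing cells, and by 0.037 to 0.086 in the other groups of cells. The median of all genes was then -0.0047 and 0.0091 in the first 2.

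Alternative settings fixed beforehand covered no cell filter, a stricter one (1000 genes, 5% mitochondrial UMIs), no doublet removal, co-expression doublets, resolutions 0.5 and 2.0, scaling within libraries, assignment by own marker score, other denominators, TMM, the mean of per-cell CPM, thinning, a pseudocount of 10, no minimum on UMIs, and other limits for named genes. Added after the data were seen were the top Scrublet scores, shares outside the low-UMI clusters, the macrophage-marker clusters pooled, the macrophage-like class without cluster 2, and collagen-expressing cells with fewer macrophage-marker UMIs. Lists of T-cell states were read in no T-cell class, since none had 100 cells per library. The HA transgene of the tumour line was not analysed here. The result of 1 gene is not reported here. Gene coordinates came from GENCODE annotation of GRCm38, the assembly that mm10 names. All 58 genes looked up matched by Ensembl identifier. Other tools were Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and matplotlib 3.10.9.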

Results

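Single-cell RNA-seq was carried out on cells that stained for CD45, the surface phosphatase carried by leukocytes, and that were sorted live from tumours of mice bearing AB1-HA cells, a mouse mesothelioma line. The 2 groups were mice given an anti-VEGF antibody, which binds the vascular growth factor encoded by Vegfa, and mice given a control antibody. Each group was represented by 1 library, so there was no replicate, no test between groups was made, and every difference describes these 2 libraries. The control library held 11687 barcodes and 233687412 UMIs (unique molecular identifiers, each counting 1 captured transcript), with a median of 17293 UMIs and 3687 genes per barcode. The anti-VEGF library held 8825 barcodes and 213948867 UMIs, with medians of 21781 UMIs and 4052 genes. The cell filter passed 10805 control and 8159 anti-VEGF cells, and 1 control cell was called a doublet. Intervals are exact 95% intervals and cover counting error only.

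The cell classes differed in share between the libraries. These are shares of sorted cells, and collagen-expressing cells need not be leukocytes, since few held a Ptprc UMI, as given below. Collagen-expressing cells made up 11.4% (interval 10.7 to 12.1, 931 cells) of the anti-VEGF library against 5.0% (4.6 to 5.43, 540 cells) of the control library. Neutrophil-like cells, which carried S100a8, S100a9 and G0s2, made up 4.09% (3.67 to 4.55, 334 cells) against 0.648% (0.505 to 0.818, 70 cells). Acp5-high cells, led by the osteoclast-associated genes Acp5 and Ctsk, were at 9.0% (8.38 to 9.64) against 11.8% (11.2 to 12.4) in the control library. Mature dendritic cell-like cells, which expressed Ccr7, Fscn1 and Ccl22, were at 0.294% (0.189 to 0.437, 24 cells) against 0.602% (0.465 to 0.766, 65 cells). These 4 classes kept the direction of their difference under every alternative that gave them a value, though its size went from 6.41 to 3.59 points for collagen-expressing cells assigned by own marker score, from 3.45 to 1.58 for neutrophil-like cells under the stricter filter, and from -2.81 to -7.17 for Acp5-high cells at resolution 2.0. Low-UMI cluster 5, with 495 control and 438 anti-VEGF cells, also carried Msln, Krt8, Cd34 and Col3a1. It was not counted among collagen-expressing cells, and counting it there was not tried as an alternative.

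Macrophage-like cells, named on detection of markers such as C1qa, Adgre1 and Apoe, were the most numerous class, at 39.4% (38.5 to 40.3) of control and 36.1% (35.0 to 37.2) of anti-VEGF cells. The direction of that difference, -3.32 percentage points, was not stable, since it was 7.35 without doublet removal (a setting that differs by 1 cell), 6.77 at Leiden resolution 0.5 and 4.79 at resolution 2.0. The class is loosely bounded. In its clusters 2, 8, 15 and 16 the best mean log2 fold of any marker class was 0.16, 0.12, 0.11 and 0.07. Monocyte-like cells, led by Mgl2, Il1b, Ly6c2 and 5 antigen-presentation genes, with all 9 macrophage markers in at least 50% of cells, were at 6.23% (5.78 to 6.70) of control and 9.29% (8.67 to 9.94) of anti-VEGF cells, and 4 alternatives formed no such class, while scaling within libraries brought the difference from 3.06 to 0.850 points. An unnamed cluster with macrophage markers, cluster 0, led by Lyz1 and Ch25h, held 8.91% (8.38 to 9.47) and 15.6% (14.8 to 16.4). All 9 macrophage markers were in 50% of its cells, but the mural marker Cspg4 among its leading genes kept it unnamed. The best-matching cluster had the opposite sign at resolution 0.5 (-0.558 points) and after removal of the top Scrublet scores (-3.18 points). Its Jaccard index (shared cells over cells in either) with cluster 0 was 0.373 and 0.227, so it held partly other cells. Macrophage-like, monocyte-like and unnamed clusters with macrophage markers, a grouping chosen after the data were seen, made up 54.6% (53.6 to 55.5) and 60.9% (59.9 to 62.0) when pooled, and the difference was -1.88 points outside the low-UMI clusters.

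Lymphocytes were few. NK cell-like cells, with Ncr1 and Prf1, numbered 60 in the control and 21 in the anti-VEGF library (0.555%, 0.424 to 0.714, against 0.257%, 0.159 to 0.393). CD8 T cell-like cells, with Cd8a and Pdcd1, numbered 9 and 11 (0.0833%, 0.0381 to 0.158, against 0.135%, 0.0673 to 0.241), a difference not detectable at this depth. Lymphocyte sub-clusters, in which 1 to 4 of the 9 macrophage markers were each detected in 50% of cells, came to 0.963% (0.787 to 1.16) and 0.674% (0.508 to 0.877), a difference that turned to 0.0782 points after removal of co-expression doublets. The other sub-clusters of the T and NK cell cluster had at least 5 of those markers and were kept as mixed, 229 cells (2.12%) in the control and 71 cells (0.870%) in the anti-VEGF library, and several were led by myeloid genes such as Cd163, Acp5 or H2-Aa. One of them, with 23 and 13 cells, was led by the regulatory T cell genes Foxp3, Il2ra and Ctla4. Plasmacytoid dendritic cell-like cells, with Siglech and Ccr9, numbered 24 and 4 (0.222%, 0.142 to 0.330, against 0.0490%, 0.0134 to 0.126), with the opposite sign, 0.416 points, where each cell was assigned by its own marker score. Type 1 conventional dendritic cell-like cells, with Xcr1 and Clec9a, stood at 0.287% and 0.221%, and mast cell- or basophil-like cells, with Cpa3 and Mcpt4, at 0.213% and 0.123%. Clusters of low UMI content, left unnamed, held 23.6% (22.8 to 24.4) of control and 12.3% (11.6 to 13.1) of anti-VEGF cells, and their difference, -11.2 points, was -2.24 under the stricter filter.

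**Figure D1:**
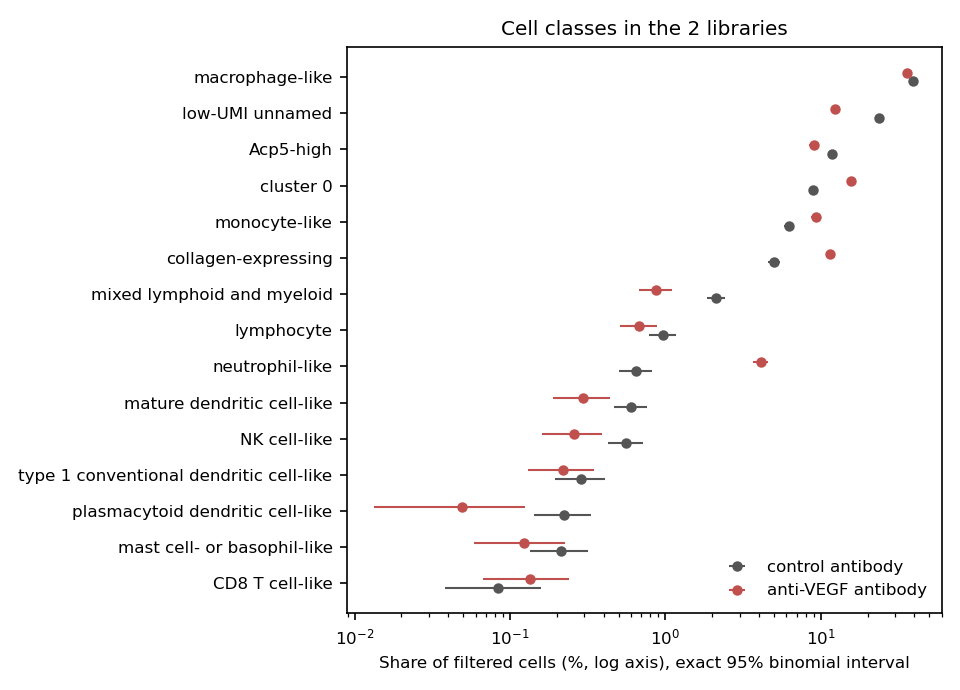
Share of filtered cells (percent, log axis) for each cell class in the control and the anti-VEGF library, with exact 95% binomial intervals that cover counting error. Collagen-expressing cells stand at 5.0% and 11.4%, neutrophil-like cells at 0.648% and 4.09%.

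In macrophage-like cells, genes of the hypoxia response were higher in the anti-VEGF library: 17 of the 18 measured members had a ratio above 1, with a median log2 ratio of 0.71. Adm, which encodes the vasodilator adrenomedullin, was 4.75-fold higher (4.47 to 5.05), Ndrg1, a gene induced by low oxygen, 4.0-fold higher (3.92 to 4.09), and Bnip3, a mitophagy receptor, 3.41-fold higher (3.33 to 3.48). Slc2a1, the glucose transporter GLUT1, went from 68.1 CPM (UMIs scaled to a common class total) in the control to 215 CPM in the anti-VEGF library, a 3.16-fold difference (3.08 to 3.25). Vegfa, which encodes the target of the antibody, was 1.48-fold higher (1.44 to 1.52; 92.4 against 137 CPM), and the exception in the list was Car9, with a ratio of 0.912 (0.817 to 1.02). All 14 measured glycolysis genes were higher, with a median log2 ratio of 0.77, among them the phosphoglycerate kinase gene Pgk1 (2.12-fold, 2.10 to 2.14), Gapdh (1.52-fold, 1.52 to 1.53) and the lactate transporter gene Slc16a3 (2.42-fold, 2.35 to 2.49). Slc2a1, Pgk1, Ldha, Aldoa and Hk2 are in both the hypoxia and the glycolysis list, so the medians of these lists are not independent in any class.

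Mmp12, which encodes macrophage elastase, showed the highest ratio among the genes named by size, at 43.8 against 281 CPM (6.41-fold, 6.22 to 6.61). It was followed by Slc7a2, a transporter of arginine and other cationic amino acids (6.07-fold, 5.70 to 6.47), Adm, Ndrg1, Ankrd37 (3.74-fold, 3.64 to 3.85) and Bnip3. Mmp12, Adm, Ndrg1, Ankrd37 and Slc2a1 are also leading genes of cluster 2, which held 936 anti-VEGF and 145 control cells. Without cluster 2 the log2 ratios were 2.52 for Mmp12 (2.65 with it), 1.66 for Adm (2.15), 1.26 for Ndrg1 (1.99), 1.48 for Ankrd37 (1.89) and 1.02 for Slc2a1 (1.65). Angiogenic factors of myeloid cells, a list that shares Vegfa and Bnip3 with the hypoxia list, had a median log2 ratio of 0.55. Of its members, 10 of 14 were higher, among them Spp1, which encodes osteopontin (2.30-fold, 2.29 to 2.31). The arginase gene Arg1 was 2.53-fold higher (2.51 to 2.55) and the inducible nitric oxide synthase gene Nos2 7.5-fold higher (6.45 to 8.75), though from 1.75 CPM. Of the VEGF ligands and receptors, 5 of 8 were higher (median log2 ratio 0.14), and the VEGF receptor gene Flt1 was at 1.09 against 4.04 CPM.

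At the other end, Fcrls, a scavenger-receptor gene of the Fc receptor-like family, had a ratio of 0.319 (0.307 to 0.331), Tmem176a 0.312 (0.294 to 0.331) and Tmem176b 0.329 (0.315 to 0.345). Npl, a sialic acid lyase gene, had a ratio of 0.534 (0.511 to 0.557), Selenop, the plasma selenium carrier, 0.550 (0.541 to 0.559) and the lipid carrier Apoe 0.561 (0.558 to 0.564). Of 9 measured genes of MHC class II presentation, 8 were lower (median log2 ratio -0.30), such as H2-Aa (ratio 0.814, 0.804 to 0.825), Cd74 (0.794, 0.788 to 0.80) and H2-DMa (0.722, 0.706 to 0.739), while the protease gene Ctss was 1.16-fold higher (1.15 to 1.17). H2-Aa, Cd74, H2-DMa, Tmem176a and Tmem176b are leading genes of cluster 3, which held 554 control and 167 anti-VEGF cells. Fcrls, Npl and Selenop are leading genes of cluster 1 (909 and 395 cells). Lower expression within clusters was not separated from the change in these cell numbers. All 20 nuclear genes of oxidative phosphorylation were lower by a small amount (median log2 ratio -0.20, or -0.090 with TMM), including Cox6c (ratio 0.856, 0.846 to 0.865). The proliferation genes were lower too, 22 of 22, at a median log2 ratio of -0.17 that ran from -0.45 without doublet removal to -0.065 with TMM, and was 0.13 once cluster 2 was left out. The 4 measured haemoglobin genes were lower (median log2 ratio -1.95), but 2016 of the 2067 control UMIs of 4 globin genes came from 1 cell.

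The hypoxia and glycolysis medians lay above all, to the precision shown, of the 10000 random lists of like size and expression (percentile 100). The angiogenic, type I interferon, alternatively activated macrophage and neutrophil lists also reached percentile 100 in macrophage-like cells (medians 0.55, 0.21, 0.21 and 0.19). The percentile alone therefore does not set hypoxia and glycolysis apart. The class II median was at percentile 0.065 and the oxidative phosphorylation median at percentile 0.31. The clusters with the most cells of the class were 12, 1 and 8 in the control (1018, 909 and 700 cells) and 2, 12 and 1 in the anti-VEGF library (936, 676 and 395 cells). The class II median was -0.61 in thinned cells and came close to 0 where cells were assigned by own marker score (-0.045) or the macrophage-marker clusters were pooled (-0.048).

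**Figure D2:**
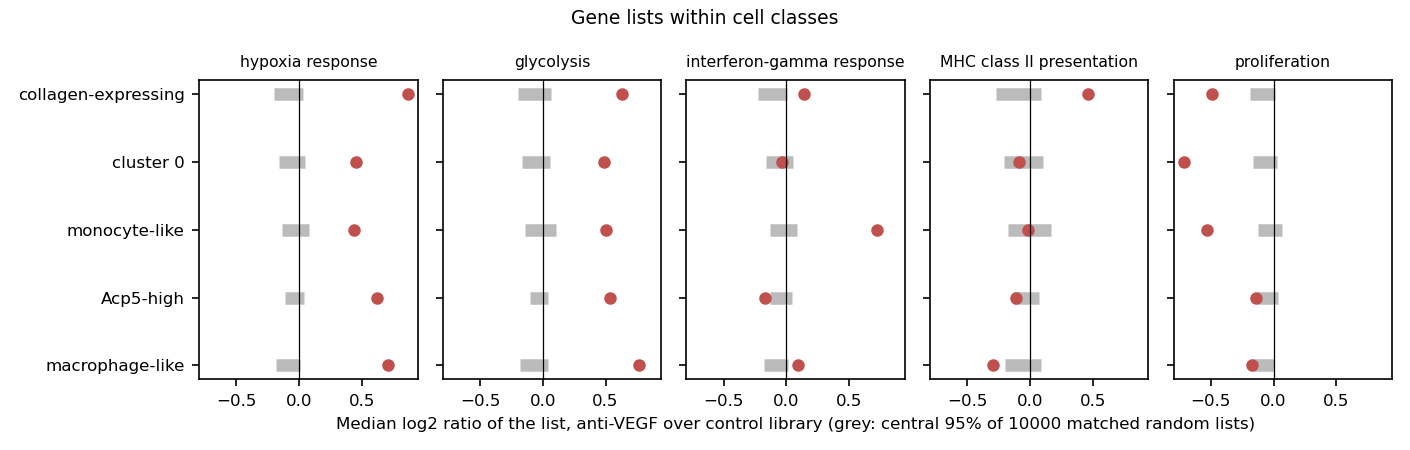
Median log2 ratio (anti-VEGF over control library) of gene lists within cell classes, with the central 95% of 10000 expression-matched random lists in grey. Hypoxia response stands at 0.71 in macrophage-like and 0.86 in collagen-expressing cells, and glycolysis at 0.77 and 0.63.

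Acp5-high cells showed the same 2 groups of genes at higher levels in the anti-VEGF library. The class joined cluster 11 (491 control and 365 anti-VEGF cells) and cluster 13 (785 and 369 cells), and no values were taken within them. Control cells of cluster 13 were shallower, at a median of 21689 against 30297 UMIs. All 18 measured hypoxia genes were higher (median log2 ratio 0.62, percentile 100), with Ankrd37 at 4.68-fold (4.10 to 5.35), Ndrg1 at 3.33-fold (3.04 to 3.64), Slc2a1 at 2.31-fold (2.12 to 2.52) and Vegfa at 1.56-fold (1.48 to 1.65). All 14 glycolysis genes were higher (median 0.54), Slc16a3 by 3.07-fold (2.77 to 3.41). Arg1 (2.52-fold, 2.41 to 2.63), Spp1 (2.45-fold, 2.40 to 2.5) and the chemokine gene Cxcl14 (2.56-fold, 2.39 to 2.76) were among the 6 highest ratios, and Selenop (ratio 0.359, 0.326 to 0.396), the small heat-shock gene Hspb1 (0.528, 0.483 to 0.577) and Apoe (0.607, 0.596 to 0.617) among the 6 lowest. All 17 genes of MHC class I presentation were lower (median -0.25), among them H2-K1 (0.762, 0.749 to 0.775), H2-D1 (0.845, 0.835 to 0.855) and B2m (0.859, 0.847 to 0.871). The mannose receptor gene Mrc1 (ratio 0.458, 0.412 to 0.508) was found in 6.14% and 4.80% of thinned cells, so its ratio rests on a minority of them, and macrophage RNA in these droplets was not tested. The chemokine gene Ccl8, at 0.548 (0.523 to 0.574), took the opposite sign in thinned cells (log2 ratio 0.34). Thinning left out 332 of 1276 control and 46 of 734 anti-VEGF Acp5-high cells, so thinned values rest on unequal parts of the class.

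Expression in the monocyte-like class had no value without doublet removal, a setting that differs by 1 cell. It also had none after removal of co-expression doublets or of the top Scrublet scores, or at resolution 2.0. The values below were therefore not checked under those settings. In monocyte-like cells, interferon-response genes were higher in the anti-VEGF library. Fewer of these cells in that library, thinned to 5000 UMIs, held the complement genes C1qa (70.2%, 66.7 to 73.5, against 80.9%, 77.7 to 83.8), C1qb (65.2% against 79.5%) and C1qc (65.4% against 79.97%). A different make-up of the class was not separated from lower expression of these genes per cell. All 19 measured interferon-gamma response genes were higher (median log2 ratio 0.72, percentile 100), such as the transcription factor gene Irf1 (1.91-fold, 1.77 to 2.06), the GTPase gene Gbp2 (2.21-fold, 2.06 to 2.38), the T-cell chemokine gene Cxcl9 (1.71-fold, 1.66 to 1.77) and Cd274, which encodes PD-L1 (1.84-fold, 1.71 to 1.98). Of 19 type I interferon genes 18 were higher (median 0.54, and 0.19 with cells assigned by own marker score), with the antiviral gene Rsad2 at 5.84-fold (4.87 to 7.04). The neutrophil and monocyte gene S100a9 was 11.6-fold higher (9.16 to 14.9), at 4.66 against 54.1 CPM and in 0.917% against 5.08% of thinned cells, Ly6a, which encodes Sca-1, 5.34-fold (4.99 to 5.72), and the platelet factor gene Pf4 4.84-fold (4.66 to 5.03). S100a9 was also at 0.321 against 17.9 CPM in Acp5-high and 5.33 against 19.6 CPM in macrophage-like cells, in the library with more neutrophil-like cells, and neutrophil RNA in these droplets was not tested. Hypoxia genes were higher here as well, 17 of 18, at a median of 0.44, with Bnip3 at 2.13-fold (2.02 to 2.24) and Vegfa at 1.10-fold (1.06 to 1.14), and glycolysis genes had a median of 0.50 (14 of 14). The fractalkine receptor gene Cx3cr1 had a ratio of 0.535 (0.509 to 0.563) and Fcrls 0.421 (0.386 to 0.460). Proliferation genes were lower, 21 of 22 (median -0.53), as were the replication gene Mcm6 (0.566, 0.509 to 0.630) and Ube2c, but under the stricter cell filter the list median was 0.038 and the log2 ratio of Ube2c 0.50.

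Cluster 0 followed the macrophage-like cells in part. Slc7a2 was 3.91-fold higher (3.48 to 4.39), Mmp12 3.19-fold (2.84 to 3.60), the lysozyme gene Lyz1 3.04-fold (2.95 to 3.13) and Arg1 2.37-fold (2.33 to 2.40). Hypoxia genes had a median log2 ratio of 0.45 (15 of 18 higher) and glycolysis genes of 0.48 (14 of 14), with Bnip3 at 1.81-fold (1.74 to 1.89) and Pgk1 at 1.77-fold (1.74 to 1.81). All 22 proliferation genes were lower (median -0.72), among them Top2a (0.642, 0.577 to 0.716) and Stmn1 (0.546, 0.527 to 0.566). The transcription factor gene Nfatc1 had a ratio of 0.451 (0.415 to 0.489). The best-matching cluster under other settings shared a Jaccard index of 0.227 to 0.597 with it, so these values describe a loosely bounded group, and the Mmp12 log2 ratio was 0.056 without the cell filter.

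Collagen-expressing cells came almost wholly from cluster 10, with 520 of 540 control and 878 of 931 anti-VEGF cells. Cluster 10 was led by Tm4sf1, Dkk2, Col3a1, Cd34 and 2 genes, Stmn2 and Baiap2l1, that also led the low-UMI cluster 5. It carried 3 of the 9 fixed mesothelial markers: Msln, which encodes mesothelin, was at 107 CPM (102.9 to 111) in the control and 98.0 CPM (94.9 to 101) in the anti-VEGF library, against 0.382 and 0.468 CPM in macrophage-like cells, the keratin gene Krt8 was at 82.1 and 94.2 CPM, and the cadherin gene Cdh2 at 49.4 and 47.0 CPM. The other 6 were absent or near it: Wt1, Lrrn4 and Gpm6a had 0 UMIs in both libraries, Upk3b 1 and 0, Krt18 63 and 6, and Krt19 7 and 44. Cluster 14 held the remaining 20 and 53 cells and had higher fibroblast matrix genes, with Dcn, the proteoglycan decorin, at 795 and 2088 CPM against 101 and 96.6 CPM in cluster 10. In cluster 10 alone, Col1a1 was at 402 CPM (394 to 411) in the control and 213 CPM (208 to 217) in the anti-VEGF library, and Col3a1 at 1646 CPM (1629 to 1662) and 1200 CPM (1189 to 1211). The few cells of cluster 14 went the other way, with Col1a1 at 774 CPM (690 to 867) and 10130 CPM (9841 to 10430), and Col3a1 at 3154 CPM (2981 to 3336) and 14420 CPM (14070 to 14770). With median depths of 3953 and 1159 UMIs, and 8 and 11 cells reaching 5000 UMIs, these values rest on few cells, and the intervals do not cover differences between cells.

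Across the collagen-expressing class, all 18 measured hypoxia genes were higher in the anti-VEGF library (median log2 ratio 0.86) and all 14 glycolysis genes (median 0.63). Car9, a carbonic anhydrase gene induced by hypoxia, was 3.98-fold higher (3.69 to 4.30), Ankrd37 3.37-fold (3.15 to 3.60), Slc2a1 2.44-fold (2.32 to 2.57) and Pgk1 2.23-fold (2.20 to 2.27), while Vegfa was 1.20-fold higher (1.15 to 1.26). The metallothionein genes Mt1 (3.85-fold, 3.79 to 3.91) and Mt2 (3.40-fold, 3.30 to 3.49), the alarmin gene Il33 (3.78-fold, 3.36 to 4.25) and the costimulatory receptor gene Tnfrsf9 (3.85-fold, 3.47 to 4.29) were also high. Genes of MHC class I presentation were lower, 16 of 17 (median -0.42), with H2-K1 at a ratio of 0.676 (0.667 to 0.686), H2-D1 at 0.739 (0.730 to 0.747) and B2m at 0.767 (0.756 to 0.777). All 22 proliferation genes were lower (median -0.49), for example Top2a (0.685, 0.664 to 0.707) and Mcm6 (0.642, 0.610 to 0.675). The matrix Gla protein gene Mgp had a ratio of 0.451 (0.440 to 0.462), and the lipid-binding gene Fabp4 one of 0.234 (0.213 to 0.257) with a log2 ratio of -2.03 that was -0.25 among cells with fewer macrophage-marker UMIs. Collagens and other matrix genes went both ways across the class, 11 of 25 higher (median -0.030, and 0.11 with TMM). These sums include cluster 14, where Col1a2, Sparc and Dcn were higher in the anti-VEGF library. In cluster 10 alone, without TMM, every fixed marker of the class was lower there. Col1a2 stood at 661 and 454 CPM, Sparc at 542 and 481 CPM, and Dcn, with little difference, at 101 and 96.6 CPM. The whole list was not measured within cluster 10. Dissociation and stress genes were lower across the class, 17 of 18 (median -0.32).

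Class II presentation genes were higher in collagen-expressing cells, 8 of 8 (median log2 ratio 0.46), such as Cd74 (1.39-fold, 1.34 to 1.43) and H2-Ab1 (1.44-fold, 1.35 to 1.54). These are macrophage genes as well, and the median was 0.077 after removal of the top Scrublet scores. Ccl6, a macrophage chemokine gene at 15.7 against 63.4 CPM (4.04-fold, 3.62 to 4.52), had a log2 ratio of 0.86 under the same setting. Haemoglobin genes had a median log2 ratio of 2.85, where 3500 of the 3742 UMIs of 4 globin genes in the anti-VEGF library came from 1 cell.

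Since the sort was on CD45, Ptprc, which encodes it, was examined in the collagen-expressing class. At 5000 UMIs per cell, 7.20% of control cells (5.04 to 9.92, 34 of 472) and 7.39% of anti-VEGF cells (5.73 to 9.36, 63 of 852) held a Ptprc UMI, with 68 and 79 shallower cells left out. Unthinned shares were 21.1% and 19.4%, at median depths of 42008 and 41008 UMIs. Macrophage-like cells held a Ptprc UMI in 54.3% (52.7 to 55.8) and 53.8% (52.0 to 55.7) of thinned cells, and lymphocytes in 97.4% (90.9 to 99.7) and 91.1% (78.8 to 98). Ptprc stood at 21.3 and 21.4 CPM in collagen-expressing cells against 171 and 159 CPM in macrophage-like cells. In the other direction, 1.79% and 2.06% of thinned macrophage-like cells (median depths before thinning, 24350 and 24584 UMIs) held a Col3a1 UMI. Among collagen-expressing cells, 87.5% and 74.3% did. These Col3a1 shares give no background for Ptprc, because macrophage-marker RNA was itself present in the collagen-expressing class. There the 9 macrophage markers stood at 0.0858 to 0.1345 (control) and 0.114 to 0.136 (anti-VEGF) of their level in macrophage-like cells. Cd34, a marker shared by fibrocytes, fibroblasts and vascular cells, was found in 75.4% (71.3 to 79.2) and 72.3% (69.2 to 75.3) of the thinned collagen-expressing cells. The Ptprc share was 1.53% and 1.19% after removal of the top Scrublet scores, and 2.65% and 3.0% under the stricter filter.

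**Figure D3:**
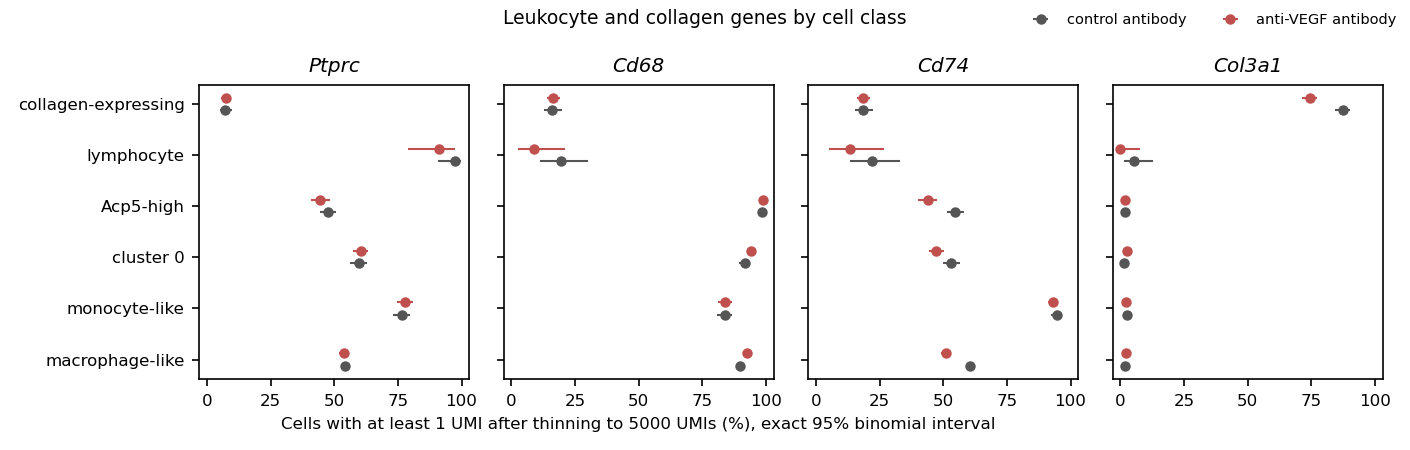
Percent of cells with at least 1 UMI of Ptprc, Cd68, Cd74 or Col3a1 after thinning to 5000 UMIs, by cell class and library, with exact 95% binomial intervals. Ptprc was found in 7.20% and 7.39% of collagen-expressing cells and in 54.3% and 53.8% of macrophage-like cells.

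By the annotation of mouse build GRCm38, Vegfa (ENSMUSG00000023951) lies on chromosome 17 from 46016993 to 46032369 and Ptprc (ENSMUSG00000026395) on chromosome 1 from 138062861 to 138175708, both on the minus strand. Mmp12 (ENSMUSG00000049723) lies on chromosome 9 from 7344381 to 7369499 and Slc2a1 (ENSMUSG00000028645) on chromosome 4 from 119108711 to 119137983. Car9 (ENSMUSG00000028463) spans 43506966 to 43513729 on chromosome 4 and Col3a1 (ENSMUSG00000026043) 45311538 to 45349706 on chromosome 1, all 4 on the plus strand. Counts were taken per gene from 3-prime tags, so no exon or isoform was resolved.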

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

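The alternatives named in the processing account as added were chosen after the data were seen. The hypoxia and glycolysis medians stayed above 0 in each of the 5 groups of cells under every alternative that gave it a value. They ran from 0.34 to 1.14 and from 0.27 to 0.87. Resolution 0.5 and scaling within libraries were applied to shares only, so no list or gene was measured under them. The differences in share kept their sign for collagen-expressing (3.59 to 6.78 points), neutrophil-like (1.58 to 4.53), Acp5-high (-7.17 to -2.81) and mature dendritic cell-like cells (-0.487 to -0.307). Among differences in share, 100 values stayed within the counting interval (99 with the same sign), 53 left it with the same sign and 12 called differences were reversed. For medians of the 5 lists followed in each class, 205 stayed within it (196 with the same sign), 77 left it (73 with the same sign) and 3 were reversals, and for the other lists the counts were 1102 (942 with the same sign), 101 (68 with the same sign) and 17. For the log2 ratios of named genes, set against the counting interval of the ratio, they were 405, 805 (804 with the same sign) and 3. With a minimum of 20 CPM instead of 50, the 12 genes named by size in a class shared 7 or 8 genes with those reported, and 12 of 12 without the minimum share of cells. Where a value moved between settings, the cause was not tested. No paired analysis was possible because there was 1 library per group and no test.

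No value could be had for monocyte-like shares under 4 settings (no doublet removal, co-expression doublets, top Scrublet scores, resolution 0.5), since no such class was formed. Its expression had none under the first 3 and at resolution 2.0. Own marker score gave no Acp5-high, mixed, low-UMI, cluster 0, NK cell-like or CD8 T cell-like class and no union of macrophage-marker clusters. NK cell-like cells also had none at resolution 2.0 or after co-expression doublets were removed, nor CD8 T cell-like cells in the latter. Type 1 conventional dendritic cell-like cells had none at resolution 0.5, with scaling, under the stricter filter or without the top Scrublet scores, nor mast cell- or basophil-like cells under the last 2. Under other clusterings, values of cluster 0 are those of the cluster that overlapped it best. Depth limits the rare classes, where 4 to 65 cells stand behind a share.

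Without the cell filter, the difference in share was 3.67 for macrophage-like, -6.95 for Acp5-high, -8.13 for low-UMI unnamed and 15.4 for cluster 0 (percentage points). List medians were -0.28 (interferon-gamma), -0.23 (MHC class II), -0.072 (inflammatory) and -0.27 (proliferation) in Acp5-high and -0.48 (MHC class II) and -0.40 (proliferation) in macrophage-like cells. List medians were 0.58 (interferon-gamma), -0.13 (MHC class II) and -0.65 (proliferation) in monocyte-like and 0.23 (MHC class II), -0.039 (inflammatory), -0.35 (proliferation), 0.27 (glycolysis) and -0.039 (neutrophil) in cluster 0. The share of collagen-expressing cells with a Ptprc UMI was 4.10% in the anti-VEGF library. Under the stricter cell filter, the difference in share was -1.06 for macrophage-like, -5.70 for Acp5-high, 5.54 for collagen-expressing and 1.58 for neutrophil-like (percentage points). It was -0.827 for mixed lymphoid and myeloid, -2.24 for low-UMI unnamed, 2.5 for macrophage-marker clusters together and 1.70 for cluster 0 (percentage points). List medians were 0.23 (MHC class II) and -0.26 (proliferation) in Acp5-high and -0.47 (interferon-gamma) and -0.39 (proliferation) in collagen-expressing cells. List medians were -0.50 (MHC class II) and -0.44 (proliferation) in macrophage-like and 0.038 (proliferation) and 0.40 (glycolysis) in monocyte-like cells. List medians were -0.33 (interferon-gamma), -0.61 (MHC class II), -0.32 (inflammatory), -0.45 (proliferation), 0.60 (glycolysis) and -0.41 (neutrophil) in cluster 0. The log2 ratio of Ube2c in monocyte-like cells was 0.50 under the stricter cell filter. The share of collagen-expressing cells with a Ptprc UMI was 2.65% in the control library and 3.0% in the anti-VEGF library. Without doublet removal, the difference in share was 7.35 for macrophage-like, -4.16 for Acp5-high, 9.16 for macrophage-marker clusters together and 1.75 for cluster 0 (percentage points). List medians were 0.072 (type I interferon) and -0.075 (interferon-gamma) in Acp5-high and -0.45 (proliferation) in macrophage-like cells. After removal of co-expression doublets, the difference in share was -5.35 for Acp5-high, 0.0782 for lymphocyte, -0.510 for mixed lymphoid and myeloid and -9.53 for low-UMI unnamed (percentage points). List medians were -0.20 (MHC class II) in macrophage-like and -0.30 (MHC class II) in cluster 0. After removal of the top Scrublet scores, the difference in share was 5.04 for macrophage-like, -5.29 for Acp5-high, 5.34 for collagen-expressing, -9.26 for low-UMI unnamed and -3.18 for cluster 0 (percentage points). List medians were -0.41 (interferon-gamma), -0.40 (MHC class II), -0.25 (inflammatory) and -0.24 (proliferation) in Acp5-high and -0.23 (interferon-gamma), 0.077 (MHC class II), -0.18 (inflammatory), -0.031 (regulatory T-cell), -0.74 (proliferation) and -0.17 (neutrophil) in collagen-expressing cells. List medians were -0.42 (proliferation) in macrophage-like and -0.34 (proliferation) and 0.56 (glycolysis) in cluster 0. The share of collagen-expressing cells with a Ptprc UMI was 1.53% in the control library and 1.19% in the anti-VEGF library. At Leiden resolution 0.5, the difference in share was 6.77 for macrophage-like, -4.62 for Acp5-high, 8.90 for macrophage-marker clusters together and -0.558 for cluster 0 (percentage points). At Leiden resolution 2.0, the difference in share was 4.79 for macrophage-like, 1.54 for monocyte-like, -7.17 for Acp5-high, -9.38 for low-UMI unnamed, 7.91 for macrophage-marker clusters together and 0.939 for cluster 0 (percentage points). List medians were -0.35 (interferon-gamma) and -0.68 (proliferation) in collagen-expressing and -0.39 (MHC class II) and -0.42 (proliferation) in macrophage-like cells. List medians were -0.71 (MHC class II), -0.036 (inflammatory), -0.47 (proliferation), 0.68 (glycolysis) and -0.40 (neutrophil) in cluster 0. With scaling within libraries, the difference in share was 7.84 for macrophage-like, 0.850 for monocyte-like, -4.26 for Acp5-high and 5.53 for collagen-expressing (percentage points). It was 2.63 for neutrophil-like, -0.835 for mixed lymphoid and myeloid, 9.12 for macrophage-marker clusters together and 0.544 for cluster 0 (percentage points).

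With cells assigned by own marker score, the difference in share was -5.79 for macrophage-like, 3.59 for collagen-expressing, 0.266 for lymphocyte, 0.416 for plasmacytoid dendritic cell-like and -1.12 for type 1 conventional dendritic cell-like (percentage points). List medians were 0.49 (interferon-gamma) and 1.02 (MHC class II) in collagen-expressing and 0.58 (hypoxia), 0.29 (interferon-gamma), -0.045 (MHC class II), -0.35 (proliferation) and 0.64 (glycolysis) in macrophage-like cells. List medians were -0.10 (MHC class II) and -0.74 (proliferation) in monocyte-like cells. The log2 ratio of H2-Aa in macrophage-like cells was 0.0049 with cells assigned by own marker score. With TMM, list medians were 0.60 (MHC class II) and -0.35 (proliferation) in collagen-expressing and -0.20 (MHC class II) and -0.065 (proliferation) in macrophage-like cells. List medians were -0.015 (MHC class II) and 0.57 (glycolysis) in cluster 0. With the mean of per-cell CPM, list medians were 0.051 (type I interferon), -0.21 (MHC class II) and -0.34 (proliferation) in Acp5-high and 0.24 (MHC class II), -0.027 (inflammatory), -0.086 (regulatory T-cell) and -0.80 (proliferation) in collagen-expressing cells. List medians were -0.57 (MHC class II) in macrophage-like cells. With thinned cells, list medians were 0.31 (MHC class II), -0.047 (complement) and -0.74 (proliferation) in collagen-expressing and -0.61 (MHC class II) in macrophage-like cells. List medians were -0.011 (MHC class II) in cluster 0. The log2 ratio of Ccl8 in Acp5-high cells was 0.34 with thinned cells. With a pseudocount of 10, list medians were 0.31 (MHC class II) in collagen-expressing and -0.41 (proliferation) in monocyte-like cells. List medians were -0.50 (proliferation) in cluster 0. With the macrophage-marker clusters pooled, list medians were 0.26 (interferon-gamma), -0.048 (MHC class II) and -0.41 (proliferation) in macrophage-like cells. With cluster 2 left out, list medians were 0.61 (hypoxia), 0.29 (interferon-gamma), -0.12 (MHC class II), -0.027 (lipid-associated), 0.13 (proliferation) and 0.57 (glycolysis) in macrophage-like cells. Among collagen-expressing cells with fewer macrophage-marker UMIs, list medians were 0.31 (MHC class II) and -0.68 (proliferation) in collagen-expressing cells.

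Outside the low-UMI clusters, the difference in share was -10.4 for macrophage-like, -5.19 for Acp5-high, -1.78 for mixed lymphoid and myeloid and -1.88 for macrophage-marker clusters together (percentage points). Among leukocyte classes, the difference in share was -7.85 for macrophage-like, -4.74 for Acp5-high, 4.46 for neutrophil-like, -1.83 for mixed lymphoid and myeloid, 3.52 for macrophage-marker clusters together and 7.92 for cluster 0 (percentage points). Within myeloid cells, the difference in share was -9.36 for macrophage-like, -5.24 for Acp5-high, 4.53 for neutrophil-like, 1.73 for macrophage-marker clusters together and 7.77 for cluster 0 (percentage points). Within lymphocytes, the difference in share was -19.5 for NK cell-like and 11.3 for CD8 T cell-like (percentage points). Without thinning, the share of collagen-expressing cells with a Ptprc UMI was 21.1% in the control library and 19.4% in the anti-VEGF library. In cells with at least 3 collagen UMIs, the share of collagen-expressing cells with a Ptprc UMI was 10.8% in the control library and 9.71% in the anti-VEGF library.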

Other observations

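The tests below were chosen after the result was seen, apart from the test of collagen-cell RNA in macrophage droplets. Genes of alternatively activated macrophages had a median log2 ratio of 0.77 in collagen-expressing (10 of 14 higher in the anti-VEGF library), 0.55 in monocyte-like (12 of 15), 0.34 in cluster 0 (8 of 11) and 0.21 in macrophage-like cells (11 of 16). In Acp5-high cells their median was -0.67 (4 of 11 higher), which took the opposite sign, 0.21, in thinned cells, as did collagen-expressing cells without the top Scrublet scores (-0.32). Leukocyte-attracting chemokines had medians of 0.24 in collagen-expressing, 0.18 in monocyte-like and 0.16 in cluster 0 cells, against -0.13 in Acp5-high and -0.11 in macrophage-like cells, and of these only the monocyte-like median kept its sign under each setting that gave a value. Complement genes had a median of 0.37 in collagen-expressing cells (10 of 12 higher), where thinned cells gave -0.047, against -0.19 in macrophage-like cells (4 of 11). Lipid-associated macrophage genes had a median of 0.15 in macrophage-like cells (12 of 16 higher), which was -0.027 without cluster 2. Checkpoint ligands and suppressive factors had a median of 0.22 in Acp5-high cells (8 of 11 higher). Costimulatory ligands lay between -0.12 in monocyte-like and 0.15 in collagen-expressing cells.

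The Wnt antagonist gene Dkk2 and the haematopoietic and stromal marker Cd34 led cluster 10. Within the class the platelet-derived growth factor receptor gene Pdgfra was at 18.3 CPM (16.6 to 20.2) in control and 14.4 CPM (13.3 to 15.6) in anti-VEGF cells of cluster 10, against 66.7 and 169 CPM in cluster 14. Mixed lymphoid and myeloid cells had under 5000 UMIs in 34.9% of control cells (28.8 to 41.5) and 7.04% of anti-VEGF cells (2.33 to 15.7). The shares were 15.5% and 6.74% in the pooled macrophage-marker clusters together with low-UMI cluster 9.

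Mesothelial or mesothelioma markers were seen in cluster 10, the main part of the collagen-expressing class. At 5000 UMIs per cell a UMI of the 9-gene list was found in 49.9% of its cells, 51.1% (46.4 to 55.7) in the control and 49.2% (45.8 to 52.7) in the anti-VEGF library, resting on Msln (35.3% and 31.0%), Cdh2 (19.4% and 20.2%) and Krt8 (9.27% and 9.75%), while Wt1, Upk3b, Lrrn4 and Gpm6a were found in 0% and Krt18 and Krt19 in at most 0.647%. Free RNA is argued against, because macrophage-like cells at the same depth held such a UMI in 0.450%. Mesothelioma or mesothelial cells carried through the CD45 sort could give such a share, but with 6 of the 9 markers nearly absent the identity of cluster 10 stays open, and low-UMI cluster 5 had a like share, 59.7% (51.2 to 67.8) and 40.7% (32.4 to 49.5). Tumour cells and host mesothelium were not separated, and an effect of the antibody on their number was not tested.

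Ptprc UMIs occurred in collagen-expressing cells. The Ptprc level there was 0.129 of that in macrophage-like cells, and in each library (0.125 and 0.135) this ratio fell within the range of the 9 macrophage markers (0.0858 to 0.134 and 0.114 to 0.136), as macrophage RNA in the same droplet would give. Ptprc expression across the class apart from macrophage RNA is argued against by the split on macrophage-marker UMIs: cells with fewer of them had 1.84 CPM of Ptprc and cells with more 44.8 CPM, a ratio of 0.0410 (0.0314 to 0.0527). These tests do not separate droplets with 2 cells from single cells that express both sets of genes, which may exist among the cells with more macrophage-marker UMIs. In cluster 5, 0.694% of 144 control cells (0.0176 to 3.81) and 2.22% of 135 anti-VEGF cells (0.461 to 6.36) held a Ptprc UMI at the same depth. Over all cells of cluster 5, the other direction was seen, with Ptprc at 20.1 CPM (15.05 to 26.3) in the control and 6.43 CPM (3.51 to 10.8) in the anti-VEGF library.

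Hypoxia genes were higher in macrophage-like cells of the anti-VEGF library. A shift of cells between clusters as the whole cause is argued against, since the lowest median log2 ratio within any of the 8 macrophage-like clusters was 0.16 (cluster 2), and the other 7 lay between 0.45 and 0.76. RNA of collagen-expressing cells could add 1.13% of the difference for the median gene (range, 0.292 to 5.44), in a test written down before its result was seen. An effect of the antibody cannot be told apart from any other difference between the 2 libraries, because there was 1 library per group.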
